A study of Mus musculus with 12 samples.

How the data were processed

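RNA was measured in 12 libraries of the mouse embryonic stem cell line E14TG2a, with 3 libraries in each of 4 groups given a control plasmid, Dux, Duxbl, or Dux together with Duxbl. Per the labels' protocols, expression from the plasmids was switched on with doxycycline (100 ng per ml) 16 h after transfection and lasted 18 h, and total RNA was prepared with a stranded kit. Groups were taken from the treatment given in the labels, and the replicate number from the sample titles. Nothing in the labels says that the 3 libraries of a group came from separate transfections or cultures, so the p-values measure the spread between these libraries, which may be technical.

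The authors deposited 1 table of 26891 genes, whose values are score data in the sense that they are whole numbers but not raw counts. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.10a, Picard 2.27.1, featureCounts 2.0.2 and DESeq2 1.30.1 were used by the authors with the mouse build mm39. The notes give no role or order for these tools, and whether counting used the strand or how multi-mapping reads were treated is not given in the sources used here. The deposited values behave as read counts divided by a size factor of each library and then rounded. The median ratio of a library to the gene means lay between 1.0065 and 1.0107, and low values fell on a ladder with a fixed step per read. The step was estimated by likelihood in each library and ran from 0.5926 to 2.012, with at least 99.74% of the values on the ladder in every library. In 12 simulated libraries the step came back within 0.013%. Where the step lies below 1, rounding merges neighbouring read numbers, so reads are estimates. Estimated totals ran from 1252260 to 3803205 reads per library, a ratio of 3.04, and genes of near-identical families can gain or lose reads to each other.

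Depth per group was 3148030 ± 256508 estimated reads in the controls, 2195510 ± 640100 with Dux, 2528193 ± 807903 with Duxbl and 2247185 ± 1364900 with both (SD, n = 3 each). A count of 0 allows up to 3 reads, which is worth 1.778 to 6.036 on the deposited scale in a single library. These floors cover counting error only.

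Genes with a value of at least 10 in at least 3 libraries were tested, which kept 13042 genes and left out 13849. The planned quasi-likelihood count test was not used, because the values are not counts. In its place limma 3.58.1 in R 4.3.3 was run on log2(value + 1) with a mean-variance trend, 1 coefficient per group and a spread shared by all 12 libraries. Fold changes are on that scale, which understates the change of low genes. The Benjamini-Hochberg adjusted p had to be below 0.05, and all adjusted p-values of single genes are from limma. The comparisons were each plasmid group against control, both plasmids against either alone, and the interaction, which is the response to Dux with Duxbl minus the response to Dux without it. Genes called Dux-raised had an adjusted p below 0.05 and a log2 fold change of at least 1 in Dux against control.

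A total of 16 gene lists, the comparisons, a first set of alternative settings and the rule for naming genes were fixed before the data were examined. The lists were two-cell genes, multi-copy two-cell families, naive pluripotency, formative and primed pluripotency, trophectoderm, primitive endoderm, germ layers, repressors of the two-cell programme, p53 targets and apoptosis, the integrated stress response, the interferon response, germline genes, fibroblast markers, skeletal muscle, replication-dependent histones, and nucleolus with ribosome biogenesis. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. The named genes were, for each comparison, up to 10 per direction with the largest changes among called genes whose groups did not overlap and whose group mean reached 5 CPM (value over library total), leaving out predicted gene models. A gene that the rule names in Dux against control is not reported. Up to 4 called members of a list, or 2 abundant ones where none was called, were added, together with the transgenes, Pou5f1, Nanog, Sox2, Zscan4c, Zscan4d, Zfp352 and Dppa3 where measured. Genes named outside this rule are marked as chosen after their values were seen. Scores per library are means of log2(value + 1) over a list and were compared with two-sided exact permutation tests, whose smallest possible p with 3 libraries per group is 0.1.

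The test was tried on simulated data with 200 changed genes in each of 10 draws. In simulated Dux against control, on a mean of 13052 genes, it recovered 19.0% of changes of 1.5-fold, 68.9% of 2-fold and 97.3% of 4-fold, and 2.38% of its calls were false. In simulated Dux plus Duxbl against Dux, on a mean of 13046 genes, it recovered 22.4%, 75.6% and 97.5%, and 8.26% of its calls were false, from 4.48% to 14.8% per draw. That is above the 5% aimed at. Counts were drawn for each gene on its own at an assumed dispersion (spread beyond counting error) of 0.02, without trends on depth, length or GC content. These rates hold for that setting and may not hold for the real libraries. At the preset correlation, the list test called 5 of 200 unchanged lists at an unadjusted p below 0.05. Genes were drawn independently of each other there, so lists whose genes move together were not tried. In the data the estimated correlation was 0.525 over naive pluripotency genes.

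Libraries of 1 group were compared for signs of a library deposited more than once. The chi-square was taken over genes with no unadjusted p below 0.05 in any comparison. Among pairs of like depth, its value over its degrees of freedom was 0.89 to 1.13 in 4 pairs of the same group. It was 0.89 to 1.55 in 14 pairs of different groups. Genes that differ between groups were thus left out beforehand, which lowers the values of the latter pairs. These values therefore cannot decide whether a library was deposited more than once, and all 12 libraries were kept as separate samples. Dux 1 with Dux 3 (0.89) and Dux plus Duxbl 1 with Dux plus Duxbl 2 (1.05), which had the lowest such values within their groups, were each also counted as 1 sample in an alternative. Control 2 with control 3 (0.97) was not, so dependence between controls was not tried. Alternatives to scaling, filter, pseudocount, samples in the fit, replicate block, depth, thinning, trend removal and single libraries were run, and their effect is given in the closing section. The alternatives on size factors in the count test and on a second count test were not run, since the deposited values already carry size factors and are not counts. Gene length and GC content were matched by identifier from an annotation of another mouse build for 99.81% of the tested genes and used only in trend removal. Chromosome positions are those of the deposited table, on mm39.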

Results

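Gene expression was measured by RNA sequencing in E14TG2a, a line of mouse embryonic stem cells, after induced expression of Dux, of Duxbl or of both. Dux is a homeobox transcription factor that activates genes of the mouse embryo at the two-cell stage, and Duxbl is a related double-homeobox protein. The series title names suppression by Duxbl of the genes switched on at zygotic genome activation, and the passage from totipotency to pluripotency. There were 3 libraries in each of 4 groups (control plasmid, Dux, Duxbl, and Dux plus Duxbl), with 1252260 to 3803205 estimated reads per library. The reads of replicates 1, 2 and 3 were 3192799, 2872085 and 3379206 in the controls and 2490929, 1461052 and 2634550 with Dux. They were 1759221, 2455275 and 3370084 with Duxbl and 1252260, 1686090 and 3803205 with Dux plus Duxbl. Values are normalised read counts, and errors of group means are SD over n = 3 libraries. Errors of log2 fold changes are SE from limma, whose adjusted p-values are given.

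Duxbl1, the gene of the Duxbl transgene (ENSMUSG00000048502, chromosome 14, 25979001 to 25990512 on mm39), stood at 41 ± 2.65 in the controls and 41.7 ± 8.96 with Dux. It stood at 890 ± 266 with Duxbl and 1130 ± 503 with Dux plus Duxbl. The log2 fold change was 4.37 ± 0.25 in Duxbl against control (adjusted p = 2.36e-09) and 4.64 ± 0.25 in Dux plus Duxbl against control (adjusted p = 1.33e-10). In all 6 libraries given Duxbl the gene held 784 to 989 estimated reads, although their depth differed by a ratio of up to 3.04. Its normalised level thus fell as depth rose and was not compared between these groups. Duxf3, the Dux gene of this annotation (ENSMUSG00000075046, chromosome 10, 58065801 to 58068497), had values of 0 to 2 in every library, including those given Dux. The Dux transgene was therefore not detectable as this gene, and the Dux groups are defined by their labels.

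**Figure D1:**
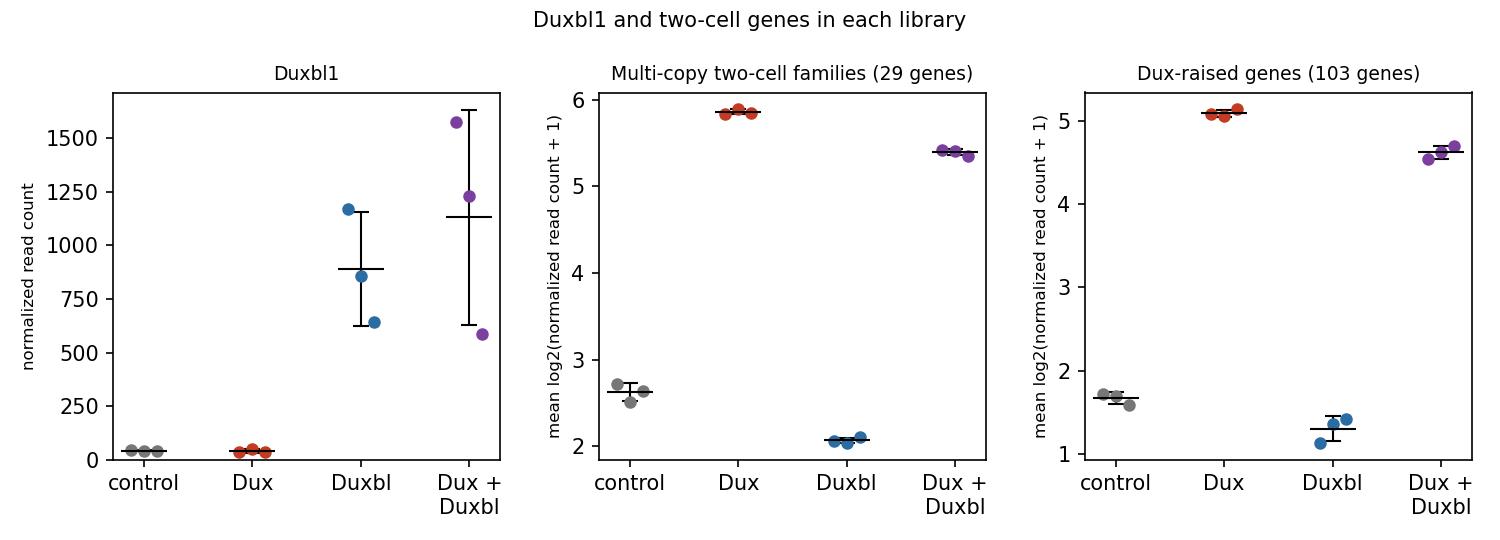
Normalised read count of Duxbl1 (left) and mean log2(normalised read count + 1) over the 29 tested genes of multi-copy two-cell families (middle) and over the 103 Dux-raised genes (right) in each of the 12 libraries by group. Points are libraries, wide lines group means and bars SD (n = 3), and the vertical axes of the middle and right panels do not start at 0. The family score was 5.86 ± 0.03 with Dux and 5.39 ± 0.04 with Dux plus Duxbl, against 2.62 ± 0.11 in the controls and 2.07 ± 0.03 with Duxbl.

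Dux against control asked which genes Dux alone changed. Of the tested two-cell genes 13 of 19 were higher, and of the tested members of multi-copy two-cell families 24 of 29. Zscan4d (ENSMUSG00000090714, chromosome 7, 10895301 to 10900086), of a family that marks the two-cell-like state of embryonic stem cells, rose from 19.3 ± 2.31 to 407 ± 59.5 (log2 fold change 4.32 ± 0.32, adjusted p = 1.67e-08). Zfp352 (ENSMUSG00000070902, chromosome 4, 90107057 to 90113939), a zinc finger gene of the two-cell embryo, rose from 1 ± 0 to 35.7 ± 2.31 (4.19 ± 0.43, adjusted p = 2.31e-06). The largest log2 fold changes among named genes were those of Zscan4-ps1 (5.77 ± 0.26), Pramel18 (5.58 ± 0.48), Pramel16 (5.14 ± 0.42), Zscan4b (5.01 ± 0.53) and AF067061 (4.93 ± 0.36). They were followed by Sp110 (4.82 ± 0.36), Usp17la (4.80 ± 0.26), Usp17le (4.48 ± 0.30), Zscan4a (4.42 ± 0.17) and Zscan4c (4.39 ± 0.27). Their adjusted p-values lay between 1.44e-12 and 3.84e-06, and each of the 10 kept its call in all 30 alternatives run. Pramel16 (ENSMUSG00000078511, chromosome 4, 143675150 to 143677586) was at 0 in all 3 controls and at 34.7 ± 7.37 with Dux, at least 47.5-fold higher than the floor of 3 reads over the control group. Many of these genes have near-identical copies, so the share of each copy is uncertain.

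Of 19 tested two-cell genes, 13 rose and 0 fell in Dux against control (14 rose and 2 fell when adjusted over the list alone). Their median log2 fold change was 2.52, with camera adjusted p = 1.73e-18 and adjusted p = 0.000303 with an estimated correlation. Besides Sp110 and AF067061 they included Gm20767 (4.35 ± 0.29) and Tmem92 (4.32 ± 0.38). Of 29 tested members of multi-copy families, 24 rose and 0 fell (24 and 1 when adjusted over the list alone), with a median of 4.03, camera adjusted p = 2.82e-46 and adjusted p = 3.03e-06 with an estimated correlation. This median stayed at 4.03 with the 3 members that were at 0 in the controls set to their bound. All 6 Zscan4 genes, all 5 Usp17l genes, all 6 Eif1ad genes and 6 of 11 Pramel genes rose, with family medians of 4.36, 4.36, 2.94 and 3.06. The 2 lists share 6 members, 2 of them tested.

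In all, 547 genes were higher and 148 lower with Dux at an adjusted p below 0.05, of 13042 tested, and 103 were at least 2-fold higher and 14 at least 2-fold lower. Of the 103 Dux-raised genes, 34 belonged to either list of two-cell genes and 44 were predicted gene models. The most reduced named gene was Scarna6, a small Cajal body RNA (ENSMUSG00000089281, chromosome 1, 87712278 to 87712542), which fell from 32.7 ± 2.52 to 7 ± 2 (log2 fold change −2.10 ± 0.30, adjusted p = 2e-04). Lefty1, a Nodal antagonist, fell from 16.3 ± 1.53 to 6.33 ± 0.577 (−1.24 ± 0.31, adjusted p = 0.0222). Others were Prrg1 (−1.65), the spliceosomal RNA U2 (−1.25), Ifitm3 (−1.14), Ndufb1 (−1.09), Chac2 (−1.04), Med31 (−0.91) and Zfp947 (−0.90), with adjusted p from 0.0105 to 0.0471. Except for Scarna6, each of these lost its call in 5 to 15 of the alternatives. The total of 695 genes fell to 277, 234 and 323 without control 1, 2 and 3, to 274 and 322 without Dux 2 and 3, and rose to 1168 without Dux plus Duxbl 3. Scaled by library size alone, which shifted the median of all genes by −0.1, 310 genes were higher and 280 lower, quantile normalisation gave 463 and 313, and voom weights on estimated reads gave 409 and 424. A fit to the groups compared alone gave 1325 and 514, and removal of trends on abundance, length and GC content left 152 and 40.

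Pluripotency genes moved by far less than the two-cell genes. Pou5f1 (0.43 ± 0.20, adjusted p = 0.224), Nanog (0.27 ± 0.15, adjusted p = 0.318) and Sox2 (0.26 ± 0.11, adjusted p = 0.177), the core factors of pluripotency, did not pass the test, and Dppa3 was too low to be tested. Of 28 naive pluripotency genes, 3 rose and 0 fell (7 and 1 when adjusted over the list alone), among them Sall4 (0.44 ± 0.10, adjusted p = 0.0101) and Klf2 (0.32 ± 0.08, adjusted p = 0.0193). The list's median was 0.26, with camera adjusted p = 9.34e-05 but adjusted p = 0.426 with an estimated correlation, and it was −0.02 once trends on abundance, length and GC content were removed. Nucleolar genes had a median of 0.18, with 3 of 30 higher (Tcof1, Ubtf and Nolc1) and 0 lower, 10 and 1 when adjusted over the list alone, camera adjusted p = 3.13e-05 and adjusted p = 0.399 with an estimated correlation. Their median was 0 with abundance and length trends removed and camera did not call them then, and Tcof1 kept its call in 29 of 30 alternatives, Ubtf in 22 and Nolc1 in 13. Of 33 repressors of the two-cell programme, 3 rose (Ehmt2, Dnmt1 and L3mbtl2, by 0.31 to 0.40) and 0 fell, 6 and 0 when adjusted over the list alone, and these 3 kept their call in 29, 17 and 9 of 30 alternatives. Their median of 0.11 had camera adjusted p = 0.0138 and adjusted p = 0.467 with an estimated correlation. Without control 1 or Dux 2 camera did not call this list (medians 0.08 and 0.06), and the median was −0.01 after quantile normalisation and −0.02 with abundance and length trends removed.

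Of 28 germline genes, 0 rose and 2 fell with Dux, the meiotic genes Sycp3 (−0.58 ± 0.12, adjusted p = 0.00762) and Meioc (−0.51 ± 0.11, adjusted p = 0.00887), and 4 fell when adjusted over the list alone. The median was −0.27, with camera adjusted p = 0.000155 and adjusted p = 0.214 with an estimated correlation. Over 31 alternatives it ran from −0.36 to −0.12, and the list lost its call in 2 of them. None of 45 replication-dependent histone genes passed limma's test, also when adjusted over the list alone. Their median was −0.25, with camera adjusted p = 0.00848 and adjusted p = 0.399 with an estimated correlation. The histone list lost its call in 8 of 31 alternatives, among them without control 1 (−0.21) or Dux 1 (−0.20), and its median ran from −0.36 to −0.02 over all of them. Single members passed in 4 more lists, namely Dnmt3b (0.30) among 16 formative and primed genes, Nes (0.37) among 8 germ layer genes, Slc7a5 (0.36) and Ppp1r15a (0.30) among 22 genes of the integrated stress response, and Eda2r (−0.37) among 25 p53 targets. Those lists had medians of 0.06, 0.22, 0.04 and −0.04 and camera adjusted p of 0.356, 0.278, 0.278 and 0.353. In the lists of trophectoderm, primitive endoderm, interferon response, fibroblast markers and skeletal muscle, limma called 0 members, and their medians of 0.06, 0.18, −0.12, 0.31 and −0.08 had camera adjusted p of 0.43, 0.356, 0.356, 0.18 and 0.481. Of these, 1 primitive endoderm gene was lower when adjusted over the list alone.

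Duxbl against control asked what Duxbl did without Dux. Beside the transgene itself, 1 gene was higher and 2 were lower, and both lower genes belong to families that Dux raised. Eif1ad8 (ENSMUSG00000079034, chromosome 12, 87561086 to 87565036) fell from 12 ± 1.73 to 4.33 ± 0.577 (log2 fold change −1.28 ± 0.20, adjusted p = 0.018). Zscan4a (ENSMUSG00000110097, chromosome 7, 10528169 to 10532984) fell from 9.33 ± 0.577 to 3.67 ± 0.577 (−1.15 ± 0.17, adjusted p = 0.0147). Map7d1, a microtubule-associated protein gene, rose from 191 ± 7.64 to 257 ± 7 (0.43 ± 0.07, adjusted p = 0.0407). Zscan4d stood at 7.33 ± 4.62 against 19.3 ± 2.31 in the controls (−1.51 ± 0.32, adjusted p = 0.09) and did not pass. Eif1ad8 and Zscan4a are at the level of a few reads with Duxbl, and their calls held in 19 of 30 and 21 of 29 alternatives, that of Map7d1 in 13 of 30. The spread behind their SE is shared with libraries given Dux alone, where Eif1ad8 stood at 108 and Zscan4a at 220. These SE and adjusted p-values may therefore understate the counting error at a few reads. Eif1ad8 did not pass without control 1, 2 or 3, Dux 1, or Duxbl 1 or 2 (adjusted p from 0.00107 to 0.17 over all its alternatives), and Zscan4a did not pass without control 1 or 2 or Dux 1 (0.000402 to 0.16).

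As a group, the multi-copy two-cell families were lower with Duxbl alone. Of the 29 tested members, 25 lay below 0, 2 fell and 0 rose, and 11 fell when adjusted over the list alone. The median log2 fold change was −0.56, with camera adjusted p = 8.73e-11 and adjusted p = 0.000835 with an estimated correlation. The median was −1.14 over the 6 Zscan4 genes, −0.80 over the 5 Usp17l genes, −0.77 over the 6 Eif1ad genes and −0.16 over the 11 Pramel genes. Tcstv3, the 1 tested Tcstv gene, lay above 0 (0.33). Under each of the 4 scalings these signs held, but quantile normalisation brought the medians to −0.60, −0.40, −0.41 and −0.09, with 4 of 6 Eif1ad genes below 0, and Tcstv3 to 0.53. Every Duxbl library scored lower than every control (2.07 ± 0.03 against 2.62 ± 0.11, n = 3 each, exact permutation p = 0.1, the smallest possible). Many members passed the filter only through libraries given Dux and stood at a few reads in both groups compared here. Usp17la stood at 3.33 in the controls and 1 with Duxbl, Zscan4f at 3.67 and 1, and Zscan4b at 1.67 and 1.33. For such genes the lower level rests on a few reads. The other list of two-cell genes had a median of −0.27, with 1 member lower (2 when adjusted over the list alone), camera adjusted p = 0.0084 and adjusted p = 0.147 with an estimated correlation, and its median was 0.01 after quantile normalisation.

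Of the remaining lists, naive pluripotency (0.14), nucleolus (0.10), trophectoderm (0.19), primitive endoderm (0.14) and repressors (0.05) had positive medians and germline genes (−0.13) a negative one in Duxbl against control. No member of these passed limma's test, with camera adjusted p from 0.00528 to 0.0369 and adjusted p of 0.147 or more with an estimated correlation. Camera did not call any of these 6 lists without Duxbl 1, the shallowest library of its group, when their medians were 0.06, 0.03, 0.17, 0.11, 0.02 and −0.10 in the same order. The other 8 lists had medians between −0.16 and 0.30, camera adjusted p of 0.0561 or more and 0 members called by limma, and 1 gene each of the nucleolus, stress response and fibroblast lists was higher when adjusted over the list alone. The count of 4 changed genes compares with 1448 at an unadjusted p below 0.05. The count was 1 without control 1, control 2 or Dux 1, 2 without Duxbl 1, 8 without Duxbl 3, 12 without Dux plus Duxbl 1 and 103 without Dux plus Duxbl 3. It was also 346 with depth as a covariate, 139 with abundance and length trends removed and 11 with voom.

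Dux plus Duxbl against control asked what remained of the response to Dux when Duxbl was given too. The two-cell programme was still high. Zscan4d stood at 341 ± 61 (log2 fold change 4.06 ± 0.32, adjusted p = 5.65e-08), Zscan4c at 109 ± 20.2 (4.11 ± 0.27, adjusted p = 3.42e-09) and Zfp352 at 16 ± 5.2 (3.03 ± 0.43, adjusted p = 0.000251). Pramel18 (5.63 ± 0.48), Zscan4-ps1 (5.29 ± 0.26), Usp17la (4.91 ± 0.26) and Sp110 (4.76 ± 0.36) had the largest log2 fold changes, and Pramel16 was at least 24.2-fold higher than the floor over the control group. Zscan4b, AF067061, Usp17ld and Pramel19 followed at 4.13 to 4.4. Of 19 two-cell genes 12 rose and 0 fell (median 2.01, camera adjusted p = 9.84e-21), and of 29 members of multi-copy families 21 rose and 0 fell (median 3.36, or 3.61 with 3 members at their bound, camera adjusted p = 1.3e-48). Adjusted over the list alone, 14 and 24 rose, and both lists held with an estimated correlation (adjusted p = 0.000197 and 2.49e-06).

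In this comparison 164 genes were higher and 11 lower. The lower ones named by the rule were Dram2 (−0.81), Aoah (−0.79), Gask1b (−0.69), Cd80 (−0.63), Sycp3 (−0.59), Gpnmb (−0.59), Ctns (−0.51), Lrrc31 (−0.50), Serpinb6c (−0.49) and Klhl24 (−0.37), with adjusted p from 0.00154 to 0.0438. Aoah, an acyloxyacyl hydrolase gene (ENSMUSG00000021322, chromosome 13, 20978283 to 21220787), fell from 76.7 ± 4.04 to 44 ± 3 and kept its call in all 30 alternatives. The other lower genes lost it in 4 to 19 of 30. Slc7a5, an amino acid transporter (0.37 ± 0.08, adjusted p = 0.0139), and Tcof1, a nucleolar protein gene (0.44 ± 0.10, adjusted p = 0.0272), were higher. Naive pluripotency (0.19), nucleolus (0.12), repressors (0.10) and germline genes (−0.23) had camera adjusted p of 0.000137, 3e-04, 0.00919 and 0.00289. With an estimated correlation their adjusted p was 0.59, 0.59, 0.634 and 0.431, and without Dux plus Duxbl 1 camera did not call the first or the third (0.12 and 0.03). The other 10 lists had medians between −0.07 and 0.15 and camera adjusted p of 0.179 or more. The total of 175 genes was 101, 86 and 99 without control 1, 2 and 3, 87 without Dux plus Duxbl 2 and 1537 without Dux plus Duxbl 3, the deepest library. Library size alone gave 125 higher and 32 lower genes, quantile normalisation 150 and 32, and removal of trends on abundance, length and GC content 101 and 12.

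Dux plus Duxbl against Dux asked whether genes raised by Dux were lower when Duxbl was given too. The Dux transgene was not measured, so any difference in its dose between these groups is part of this comparison. Single genes did not pass in that direction, while the set did lie lower. Limma called 1 gene higher, the Duxbl1 transgene (4.63 ± 0.25, adjusted p = 7.87e-10), and 0 lower, beside 364 higher and 460 lower at an unadjusted p below 0.05. None of the 103 Dux-raised genes was called lower, and 88 of them lay below 0, with a median log2 fold change of −0.41 (quartiles −0.76 and −0.17). The per-library score over these genes was 4.62 ± 0.08 with both plasmids and 5.1 ± 0.04 with Dux, without overlap (n = 3 each, exact permutation p = 0.1, the smallest possible). Since the genes were chosen on the Dux libraries, a lower value elsewhere is in part expected from the choice. In 50 simulations with the Dux plus Duxbl libraries drawn at the Dux level, the median over a mean of 137 chosen genes was −0.07 on average (−0.17 to 0.03), with 79.5 of them below 0 and 0 called lower. Genes were drawn independently there, while the 103 genes had an estimated correlation of 0.0267. Shifts shared by a whole library were thus left out, and the simulated range may be too narrow.

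The multi-copy families, whose members were listed before the data were examined, also lay lower with both plasmids than with Dux. Of their 29 tested members, 24 are among the 103 Dux-raised genes, so the results of these sets are not independent. Their median log2 fold change was −0.39, with 24 of 29 members below 0 and 0 called by limma over all genes, 5 lower when adjusted over the list alone, camera adjusted p = 6.38e-06 and adjusted p = 0.00697 with an estimated correlation. Some members passed the filter on low values through the Dux libraries. With the filter set on the other libraries, 23 members were kept, with a median of −0.31, 18 below 0, camera adjusted p = 9.97e-05 and adjusted p = 0.0372 with an estimated correlation, and the 3 Eif1ad genes kept had a median of −1.07. The median over the 6 Eif1ad genes was −0.92 with all 6 below 0, as in Eif1ad8, which stood at 51 ± 2.65 with both plasmids and 108 ± 11 with Dux. It was −0.40 over the 6 Zscan4 genes with all 6 below 0, −0.21 over the 5 Usp17l genes with 3 below 0, and −0.17 over the 11 Pramel genes with 8 below 0, and under the other scalings these medians stayed below 0. Zfp352 differed by −1.16 ± 0.43 (adjusted p = 0.714), Zscan4c by −0.29 ± 0.27 (adjusted p = 0.901) and Zscan4d by −0.26 ± 0.32 (adjusted p = 0.941). The list of two-cell genes had a median of −0.11, with 0 called by limma and 4 lower when adjusted over the list alone, camera adjusted p = 0.0201 and adjusted p = 0.245 with an estimated correlation, and camera did not call it without Dux 1 or 3 or Dux plus Duxbl 1 or 3 (−0.23 to −0.06). Histone genes had a median of 0.16, with 0 called, camera adjusted p = 0.000835 and adjusted p = 0.333 with an estimated correlation, and were not called without Dux 1 (0.14). Pou5f1, Nanog and Sox2 differed by 0.01, −0.07 and 0.02. The other lists had medians between −0.11 and 0.06, with camera adjusted p of 0.148 or more. Beside the 0 genes that limma called lower, voom called 7 lower, all 7 of them Dux-raised by its own fit, a fit to the groups compared alone called 6, and depth as a covariate called 5, of which 2 were Dux-raised. Pseudocount 4 and removal of trends on abundance, length and GC content called 2 each, and the fit without Dux plus Duxbl 3 called 1. The count of genes called in either direction, 1 in all, was 2 without Dux 1 or without Dux plus Duxbl 3.

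Dux plus Duxbl against Duxbl gives the response to Dux in cells that also had Duxbl, in libraries that did not choose the Dux-raised genes. Usp17la (5.97 ± 0.26), Zscan4-ps1 (5.82 ± 0.26), Zscan4d (5.57 ± 0.32), Pramel18 (5.25 ± 0.48) and Usp17le (5.18 ± 0.30) had the largest log2 fold changes, with adjusted p from 6.91e-12 to 3.54e-07. Pramel19, Usp17lb, Zscan4e, Zscan4b and AF067061 followed at 4.81 to 5.15. Limma called 98 genes higher and 0 lower, beside 297 and 353 at an unadjusted p below 0.05, and voom called 108 and 0. Without Dux plus Duxbl 3 limma called 96 higher and 45 lower, and without Duxbl 2 it called 92 and 1. Of 19 two-cell genes 12 rose (median 2.57) and of 29 members of multi-copy families 22 rose (median 3.36), 14 and 24 when adjusted over the list alone, with 0 lower in either. Camera adjusted p was 1.11e-46 and 6.29e-113, and 8.46e-06 and 8.38e-08 with an estimated correlation. Of the 103 Dux-raised genes, 90 were called higher, and their median log2 fold change was 3.24, beside 3.30 in Dux against control. With the genes at 0 in all libraries of the lower group set to their bound, 10 against Duxbl and 4 against control, these medians were 3.24 and 3.34. The other 14 lists had medians between −0.23 and 0.08, with camera adjusted p of 0.138 or more.

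**Figure D2:**
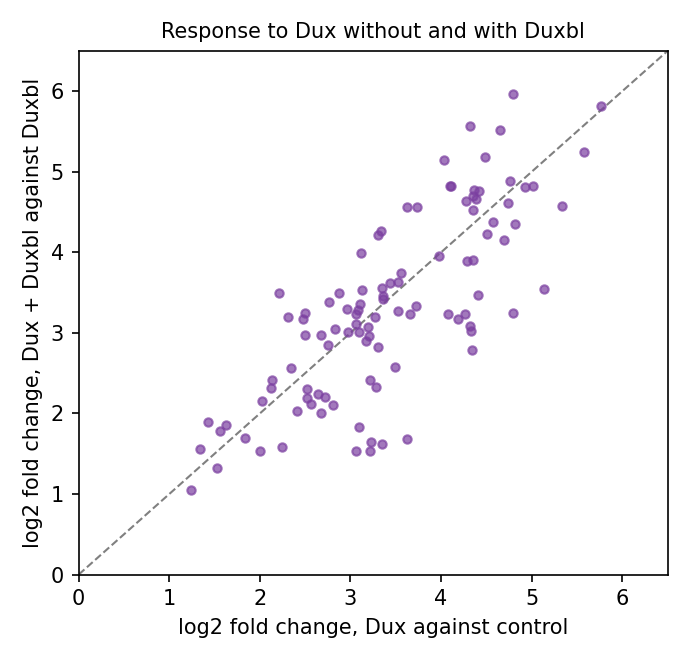
Log2 fold change of each of the 103 Dux-raised genes in Dux against control (horizontal axis) and in Dux plus Duxbl against Duxbl (vertical axis), on the log2(normalised read count + 1) scale. Each point is a gene and the dashed line marks equal responses; the genes were chosen for a log2 fold change of at least 1 on the horizontal axis (median 3.30), and on the vertical axis, whose libraries did not choose them, all 103 lie above 0 (median 3.24).

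The interaction tests whether the response to Dux differed between cells with and without Duxbl. Limma called 0 genes, beside 595 above and 862 below 0 at an unadjusted p below 0.05, and voom also called 0. Over the Dux-raised genes the median interaction was −0.03, with 52 below 0 and 51 above. Over the multi-copy families it was 0.25, with camera adjusted p = 0.0758. Zscan4d had an interaction of 1.24 ± 0.45 (adjusted p = 0.311) and Zfp352 one of −1.02 ± 0.61 (adjusted p = 0.548). Thus the lower level of these families with both plasmids than with Dux stood beside a lower level with Duxbl than in the controls. Both responses to Dux are measured from groups where many of these genes had few reads. Of the 103 Dux-raised genes, 10 were at 0 in all Duxbl libraries and 4 in all controls. The interaction may therefore depend on the pseudocount, and a median near 0 does not show that Duxbl left the response unchanged. With depth as a covariate 395 genes had an interaction, 325 of them negative, and with abundance and length trends removed 56 had one.

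Dux and Duxbl were also compared for genes they changed in common, leaving out the Duxbl1 gene. Map7d1 rose in both, and 0 genes fell in both, where independent lists would share 0.0419 and 0.0227 genes. Simulated unchanged groups against the same controls shared 0.04 and 0. Across 13041 genes, which are not independent replicates, the fold changes correlated with r = 0.28, where shared controls alone gave 0.5 in simulation. The simulated groups held no response to Dux, and changes with Dux alone lower r. The 2 values of r therefore cannot show whether the responses were shared. The covariance of the fold changes was 0.0272 against a simulated 0.0212, a difference of 0.00595, and 77.3% of genes had the same sign against a simulated 66.7%. The 3 controls cannot be split so that each part keeps 2, so part of the excess may come from the shared controls. The shared count was 0 without control 1, control 2, Dux 1, Dux 2, Duxbl 1, Duxbl 2 or Dux plus Duxbl 2, 3 without Duxbl 3, 8 without Dux plus Duxbl 1 and 92 without Dux plus Duxbl 3.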

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

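The 6 results below come from tests fixed before the data were examined, and the depth covariate was chosen after the results were seen. They are gene lists whose response to Dux differed between cells with and without Duxbl by camera at its preset correlation, with 3 libraries in each of 4 groups. The median interaction was −0.16 over naive pluripotency genes (camera adjusted p = 0.0197), −0.15 over nucleolar and ribosome biogenesis genes (0.00576), −0.2 over the integrated stress response (0.0248) and −0.34 over fibroblast markers (0.0476). It was 0.17 over germline genes (0.0131) and 0.23 over replication-dependent histones (0.00572). With an estimated correlation none of the 6 passed, with adjusted p of 0.585, 0.523, 0.212, 0.212, 0.212 and 0.212 in the order given. No member of these lists had an interaction called by limma over all genes, beside 1457 genes at an unadjusted p below 0.05 and 0 called by voom. Adjusted over the list alone, 1 gene was below 0 among the nucleolar genes and 1 among the fibroblast markers.

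Other splits of the 12 libraries cannot test the interaction, since any split gives at least the 0 genes of the real one (100 of 100 did), and the 661 genes of the highest other split mix in the response to Dux. With depth as a covariate, 395 genes had an interaction, 70 above and 325 below 0, and the cause was not tested.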

How the results depend on the processing

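Alternatives with pseudocounts 0.5 and 4, quantile normalisation, TMM, voom, depth as a covariate, trend removal, the shallowest libraries left out, libraries counted as 1 sample or a filter without the Dux libraries were chosen after the data were seen. The multi-copy two-cell families kept their direction and their call under all 31 alternatives in Duxbl against control (−0.73 to −0.29) and in Dux plus Duxbl against Dux (−0.51 to −0.30). They also did so, above 0, in the 3 comparisons of Dux with cells lacking it, but the size of the median varied widely. It ran from 2.06 to 4.17 in Dux against control, from 1.19 to 3.7 in Dux plus Duxbl against control and from 1.57 to 4.66 against Duxbl. Over all alternatives, results of single genes kept direction and side of the threshold in 6402 cases, lost a call in 355, gained one in 55 and turned in 3. Those of lists did so in 2288, 113, 68 and 11. Depth limits genes with few reads, and the cause of the changes below was not tested, except that a fold limit can only lower a count. The alternatives on size factors in a count test and on a second count test were not run, since the values are not counts.

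Leaving out 1 library, the genes changed ranged from 234 to 1168 in Dux against control (lowest without control 2, highest without Dux plus Duxbl 3). They ranged from 1 to 103 in Duxbl against control (highest without Dux plus Duxbl 3) and from 86 to 1537 in Dux plus Duxbl against control (lowest without control 2, highest without Dux plus Duxbl 3). They ranged from 1 to 2 in Dux plus Duxbl against Dux and from 87 to 141 against Duxbl. The interaction and the Dux-raised genes lower with Duxbl stayed at 0. The median response of Dux-raised genes with Duxbl present ranged from 3.15 to 3.38, the overlap of Dux and Duxbl from 0 to 92 and the called lists from 20 to 32. In Dux plus Duxbl against Dux without Dux plus Duxbl 3, naive genes (−0.04 in full) had 0.09 and repressors (−0.01) 0.1, while without Dux plus Duxbl 1 they had −0.13 and −0.08.

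The overlap, 1 gene in full, was 0 with library size only. No filter gave an overlap of 0 and a median response of 2.41, and a CPM filter 0 and 2.62, each with its own Dux-raised genes. A replicate block gave 18 genes in Duxbl against control, 316 in Dux plus Duxbl against control and an overlap of 12. A fit to only the groups compared gave 1839 in Dux, 76 in Duxbl and 84 in Dux plus Duxbl against control, and 7 in Dux plus Duxbl against Dux. A log2 fold change of at least 1 left 117 with Dux, 92 with both and an overlap of 0. Thinning to the smallest library left 311 with Dux, 111 with both, a median of 3.44 and an overlap of 2. Without the 10 most abundant genes and the transgenes there were 2 in Duxbl against control, 0 in Dux plus Duxbl against Dux and an overlap of 0. With an estimated correlation 8 lists passed, of 26.

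Pseudocount 0.5 gave a median of 3.85. Pseudocount 4 gave 1.95, 1 gene in Duxbl against control, 3 in Dux plus Duxbl against Dux, 2 Dux-raised genes lower with Duxbl and an overlap of 0. Quantile normalisation gave 10 genes with Duxbl, 2 in Dux plus Duxbl against Dux, a median of 2.53, an overlap of 8 and 16 lists, with repressors at −0.01 in Dux and two-cell genes at 0.01 in Duxbl against control. The depth covariate gave 346 genes with Duxbl, 358 with both, 10 in Dux plus Duxbl against Dux, 395 interactions, 2 Dux-raised genes lower and an overlap of 274. Voom gave 11 with Duxbl, 8 in Dux plus Duxbl against Dux, 7 Dux-raised genes lower, a median of 3.88 and an overlap of 9.

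With abundance and length trends removed there were 1100 genes with Dux, 139 with Duxbl, 404 with both, 56 interactions, a median of 2.71, an overlap of 114 and 16 lists. Repressors stood at −0.02, Nanog at −0.2 and Ttn at 0.11 with Dux, nucleolar genes at −0.01 with Duxbl and Rif1 at −0.14 with both. With the GC trend removed as well there were 192 with Dux, 1 with Duxbl, 113 with both, 3 in Dux plus Duxbl against Dux, 2 Dux-raised genes lower, a median of 2.93, an overlap of 0 and 11 lists. Naive genes then stood at −0.02 with Dux and −0.02 with Duxbl, and repressors at −0.01 with Dux, −0.01 with Duxbl and −0.01 with both. Without the shallowest library of each group given Dux or Duxbl there were 8 with Duxbl, an overlap of 3 and 16 lists. Dux 1 and 3 as 1 sample gave 376 with Dux. Dux plus Duxbl 1 and 2 as 1 sample gave 10 with Duxbl, 101 with both and an overlap of 6.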

Other observations

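The tests of slopes on depth and of a common ratio, the depth covariate and trend removal, and the genes in the first paragraph, were chosen after the values were seen. Among the Dux-raised genes, the 5 that stood lowest with Dux plus Duxbl relative to Dux were Gm11543 (18.7 with Dux and 4 with both, log2 difference −2.60), Eif1ad11 (14 and 3.33, −1.93), Spopfm1 (29.3 and 7, −1.92), Phf11a (12.3 and 3.33, −1.86) and Eif4a3l1 (22.7 and 7, −1.73), all at low levels. At higher levels, Tmem92 stood at 65.3 and 23.7 (−1.44) and Eif1ad15 at 95 and 43 (−1.13). Others stood level, such as Pramel18 (99 and 103, 0.06), Usp17la (115 and 124, 0.11) and Sp110 (80.7 and 77.3, −0.06). None of these differences passed limma's test, with 460 genes lower at an unadjusted p below 0.05 and 7 called lower by voom. Of the 6 tested Eif1ad genes all lay below 0 in this comparison, from −1.93 to −0.38, and of the 11 Pramel genes 8 did.

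The families of two-cell genes with many copies lay lower with Duxbl, both without Dux (−0.56) and with it (−0.39). Without Dux the difference rests on a few reads for many members. With depth as a covariate the medians were −0.62 and −0.41. Camera with an estimated correlation still gave the list an unadjusted p below 0.05 in both comparisons. With Dux, where the depths of the 2 groups overlapped, this argues against a difference in depth as the whole cause. Without Dux, only Duxbl 3 (3370084 reads) reached the depth of the controls (2872085 to 3379206). The covariate is 1 slope per gene over all 12 libraries, so it cannot decide there. A smaller share of cells with active Dux in the libraries given both plasmids would lower all Dux-raised genes by a common ratio, and the fitted ratio was 0.72. The spread of their log2 differences (0.57) was reached by a share of 1e-04 of 10000 simulations, the smallest share above 0 they can give. Their highest spread was 0.58 and the simulated noise is an assumption, so a smaller share of such cells may still be part of the cause. The Dux transgene was not measured, so a lower dose of Dux in these cells and an effect of Duxbl on these genes, the biological explanation that the groups name, both stay open.

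Within groups, the level of abundant genes fell as depth rose. On log2 depth the 1305 most abundant genes had a median slope of −0.15, and Duxbl1 held 784 to 989 estimated reads in libraries whose depth differed by a ratio of 3.04. Rounding and the pseudocount act on low genes, so that slope of −0.15 argues against them for abundant genes, while for the 6521 least abundant genes, with a slope of 0.13, they stay open. Loss of reads as duplicates could act most where reads lie densest. Among abundant genes the slope was −0.19 in the 1087 shortest and −0.02 in the 1088 longest, a difference of −0.16, as this explanation needs. No biological explanation was tested, and level differences of abundant genes between groups of unlike depth may be off by this much.

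Many genes shifted together in the 3 groups given Dux or Duxbl relative to the controls. These groups share the controls, which alone makes genes shift together. Between Dux and Duxbl the fold changes correlated with r = 0.28. Shared controls gave 0.5 in a simulation without a response to Dux, which lowers r, so these 2 values cannot be set against each other. The covariance was 0.0272 against a simulated 0.0212, and 77.3% had the same sign against a simulated 66.7%. Across genes, which are not independent replicates, the mean shift had a Spearman correlation of 0.39 with GC content and of −0.45 with the slope on depth within groups. Both explanations had these signs or sizes stated beforehand, although slopes on depth were themselves taken up after values were seen. In Dux against control, with depth as a covariate, 970 genes passed, not 695, and 612 of the 695 still did (median size 0.35 on the log2 scale, before 0.39). Depth did not overlap between these groups, with 2872085 to 3379206 reads in the controls and 1461052 to 2634550 with Dux. The covariate therefore cannot tell depth from Dux as the cause of these calls. Removal of abundance and length trends gave 1100 genes, and with the GC trend removed as well 192 passed: 546 calls ended because the size fell, from a median of 0.37 (quartiles 0.32 and 0.43) to 0.17 (0.10 and 0.27), while the median SE went from 0.09 to 0.07. Removal of abundance and length trends alone had already taken these 546 genes to a median of 0.30, with 434 of them still called. GC content may thus account for part of the smaller changes. Depth, the spread of the shared controls and a response to either plasmid that the groups share stay open.

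Other splits of the 6 libraries of each comparison were tried, and 10 splits cannot give a share under 0.05. In Dux against control 1 of 10 splits, the real one, gave as many as 695 genes and the highest other 0. In Duxbl against control the real split gave 4 genes and the highest other 0 (1 of 10), and in Dux plus Duxbl against control 175 and 0 (1 of 10). In Dux plus Duxbl against Dux, 2 of 10 splits gave as many as the real 1 gene, and the other one gave 448, parting Dux 1, Dux 3 and Dux plus Duxbl 3 (mean 2976228 reads) from Dux 2, Dux plus Duxbl 1 and Dux plus Duxbl 2 (1466467). Against Duxbl, 2 of 10 gave as many as the real 98, and the other one gave 1197, parting Duxbl 1, Dux plus Duxbl 1 and Dux plus Duxbl 2 (1565857) from Duxbl 2, Duxbl 3 and Dux plus Duxbl 3 (3209521). Both of these splits follow depth, and with depth as a covariate the real counts were 10 and 113.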
